A study of Homo sapiens with 2 samples.

How the data were processed

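Gene expression was measured in ARPE-19 cells with 2 arrays, 1 of a sham-washed control and 1 of cells that received 1 µM adriamycin for 24 h, per the labels. The groups came from the samples' titles. The arrays were 1-colour (Cy3) Agilent arrays of design 039494, whose probes are annotated on the human genome build hg19, per the file headers. They shared a slide and a scan. With 1 array per group, culture, RNA preparation, labelling and place on the slide cannot be told apart from the treatment.

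The deposited scanner files hold an intensity per spot. Per the file headers and the submitters' processing notes, Agilent Feature Extraction 10.7.1.1 measured each spot, subtracted a spatially fitted background, detrended the signals within the array and gave a surrogate value to signals not above background. It did not normalise between arrays. The deposited value table holds log2 values, 1 column per sample, and how the authors made it is not given in the sources used here. Set against the scanner files, its values were log2 processed signals, averaged to 50739 probes and quantile normalised over both arrays, since the sorted columns differed by at most 0.0014 and both had a median of 4.90. The values were not centred per gene. The column headed control correlated with the adriamycin array at 0.9999 and with the control array at 0.951, and the column headed adriamycin with the control array at 0.9999 and with the adriamycin array at 0.951. The direction of the table therefore stands opposite to the scanner files, and which of them carries the right headings stays unknown from the files' own statements. The scanner files, each assigned to its sample in the record, were used for the main values. The value table served as an alternative, with each column given to the array it matched.

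Spots flagged as outliers (357 on the control and 504 on the adriamycin array) and control spots were left out, and no spot was saturated. The log2 processed signals of a probe were averaged over its spots, of which 902 probes had 10. The 75th percentile over the 50527 probes used was then subtracted from each array; 72 probes had outlier spots only. A gene was represented by its probe with the highest mean level over both arrays and was counted where at least 50% of that probe's spots were well above background on both arrays. Gene names were updated through RefSeq transcript accessions, symbols or unambiguous synonyms of assembly GRCh38.p14, used for names, neighbours and gene biotypes only. This named 31412 probes, 28174 by accession, 2618 by symbol and 620 by synonym, and 19187 kept the name of the array's design, for 36363 gene names in all. Probe coordinates are those of the files on hg19.

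With 1 array per group no test, p-value or replicate error was possible. Genes were counted at a fixed size, 2-fold. Each of 34 gene lists was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size, drawn from 20 bins of mean level. The within-array spread came from probes with at least 5 usable spots on both arrays. The named genes were MDM2, CDKN1A, TOP2A and TOP2B; the 15 highest and 15 lowest ratios among genes with plain symbols whose detected probes lay on the same side of 0; the 5 highest and 5 lowest bounds among genes detected on 1 array only; and up to 4 members with the largest ratio in size of each list. Some genes that this rule names are not reported here. These rules, the lists and most alternatives were fixed before the data were examined. On simulated ratios at the real genes' levels, 200 of 19421 genes were altered and a small noise was added. The count recovered 0% of genes shifted by 0.50 on the log2 scale and 100% of those shifted by 1.50 or 3.00. That noise was far smaller than the distance of these shifts from the 2-fold limit, so the outcome was fixed in advance. It checks the calculation and does not measure how well real differences are recovered. Of 20 random lists of 30 genes in the real ratios, 0 passed the 97.5th percentile with no shift added, 16 with an added shift of 0.50 and 20 with one of 1.00.

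The alternatives were normexp background correction (offset 50) on mean and background signals, median scaling, quantile normalisation, cyclic loess, scaling on the E1A spike-in probes, the percentile over detected probes, no filter and a stricter filter on dim probes, the mean over a gene's probes, the probe with the smallest ratio, the value table, and thresholds of 1.5-fold and 4-fold. Leaving out spots in patches (3 or more neighbours within 75 µm that differed at least 16-fold the same way, with single spots scaled on the 75th percentile over spots, 713 on the control and 654 on the adriamycin array), using rows past the middle of the array, and the value table as headed were added after the data were seen. Of the 10 spike-in probes, 8 were well above background on both arrays, and scaling on them moved every log2 ratio by −0.075. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.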

Results

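The study measured messenger RNA in ARPE-19 cells, an established human cell line from the retinal pigment epithelium, the layer of pigmented cells behind the photoreceptors of the eye. Per the labels, 1 culture received 1 µM adriamycin for 24 h and 1 was a sham-washed control. Adriamycin (doxorubicin) is an anthracycline that intercalates into DNA and traps topoisomerase II on it. Each RNA was hybridised to 1 array of the same 1-colour Agilent design, and both arrays lay on the same slide and were scanned together. With 1 array per group there is no replicate check of any difference, and the number of arrays limits the precision of every value. All statements below therefore describe these 2 arrays. Each array held 62976 spots, of which 58717 were not controls, for 50599 probes. The 75th percentile of the processed signal over probes was 436 on the control array and 418 on the adriamycin array. Well above background were 28558 probes (56.5%) on the control array and 27873 (55.2%) on the adriamycin array. Signals are given below as log2 levels relative to the array's own 75th percentile, and a log2 ratio is the adriamycin level minus the control level.

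The comparison of adriamycin with control asks how 24 h with the drug goes with messenger RNA levels in these cells. Of 19421 genes well above background on both arrays, 2560 (13.2%) were at least 2-fold higher and 1940 (9.99%) at least 2-fold lower on the adriamycin array. A further 14921 lay within 2-fold. At least 4-fold higher were 819 genes and at least 4-fold lower 302. The highest ratios, for PRODH, AKR1B15, GDF15, AKR1B10 and FXYD3, ranged from 259-fold to 441-fold. These directions follow the scanner files as they are assigned to the samples; the authors' value table, with its columns as headed, has the opposite direction for nearly every gene (correlation of the log2 ratios across 25639 probes, −0.993). Across genes, which are not independent replicates, the levels on the arrays correlated with r = 0.940. Spots of the same probe gave the only measured error. Over 679 probes with replicate spots, the log2 ratio of single spots had a median SD of 0.069. Of single spots, 0.143% deviated by 1 or more. These values left out flagged outlier spots and dim probes, so they may understate the error of other probes. Without these limits, some spots of probes present 10 times lay at least 1 above their probe's median log2 signal. On the adriamycin array these were 3.34% in rows up to the middle and 0.46% past it. Different probes of a gene differed more. In 4600 genes, the 2 brightest detected probes differed by a median of 0.246 on the log2 scale, and 11.5% of these pairs by 1 or more. A median scaling in place of the 75th percentile moved every log2 ratio by −0.30, and the split became 1747 higher and 3328 lower (34.4% higher, against 56.9% in the main setting).

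**Figure D1:**
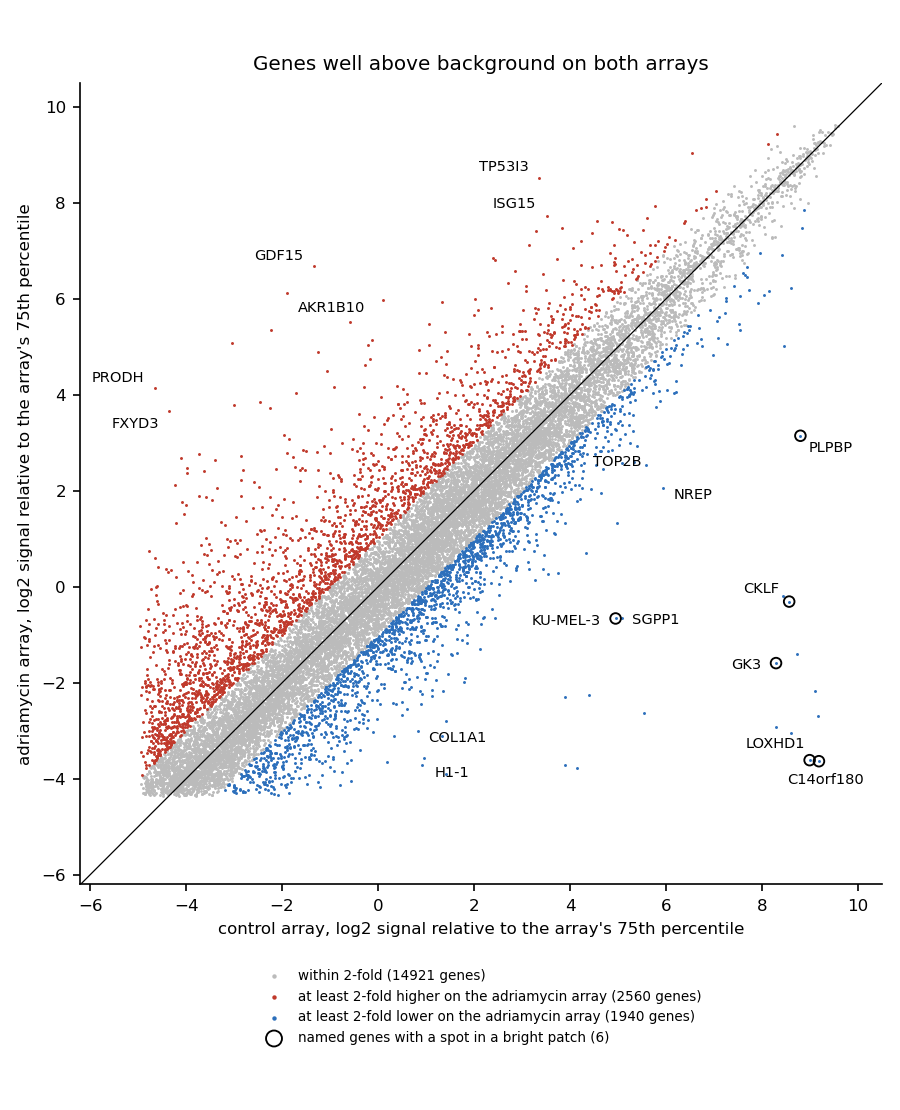
Log2 signal of each gene relative to the array's 75th percentile, control array on the x axis and adriamycin array on the y axis, for the 19421 genes well above background on both arrays. Points are genes, coloured by 2-fold difference, the line marks equal levels, and circles mark the 6 named genes with a spot in a bright patch of the control array; 2560 genes lie at least 2-fold above the line and 1940 at least 2-fold below it.

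The 15 highest ratios were led by PRODH, a mitochondrial proline dehydrogenase, at 441-fold (log2 levels −4.65 on the control and 4.13 on the adriamycin array). Its other probe gave a log2 ratio of only 0.65. AKR1B15 and AKR1B10, neighbouring aldo-keto reductase genes with near-identical sequences, were 277-fold and 259-fold higher, and each value is uncertain for that reason. GDF15, a secreted stress cytokine, was 261-fold higher, with a control level of −1.34 and an adriamycin level of 6.69 (probe on chromosome 19, hg19 positions 18499890 to 18499949). FXYD3, a regulator of the sodium pump, was 259-fold higher (chromosome 19, 35614472 to 35614531). DHRS2, a short-chain dehydrogenase, was 190-fold higher, the lens crystallin gene CRYBA1 110-fold, and the glutaminase gene GLS2 110-fold. The lipoxygenase gene ALOX5 was 78.8-fold higher over 10 spots. LCN15 (81.8-fold), the fatty acid hydroxylase gene FA2H (81.5-fold), PGF, a placental growth factor (70.7-fold), AREG, a ligand of the epidermal growth factor receptor (65.5-fold), and LRATD1 (62.5-fold) were also among them. The 4 probes of LRATD1 spanned log2 ratios from 1.68 to 5.97. On the control array, the 15 genes had processed signals from 17.4 (PRODH) to 184 (PGF). Those of PRODH, FXYD3 (21.3) and FA2H (23.4) lay below the highest of 308 negative control spots there, 23.9, so the size of their ratios is uncertain although each was called well above background. Well above background on the adriamycin array only, and so with a bound, were NTN1, which encodes the guidance cue netrin (at least 213-fold higher), SCN4B (at least 210.2-fold), NSG1 (at least 124-fold), the imprinted noncoding RNA H19 (at least 92.1-fold) and INSYN2A (at least 85.7-fold). Each bound sets the bright level against the higher of the dim probe's own level and the level of the lowest single spot called well above background on its array. Of the 15 highest genes and these 5, 18 had 1 spot, in 11 cases in the rows up to the middle of the array. Within 75 µm, CRYBA1 and SCN4B each had 1 other spot at least 16-fold brighter on the adriamycin array, and within 300 µm NSG1 had 21, AREG 12, NTN1 10 and FXYD3 7, as counted after the data were seen. Of the 10 spots of ALOX5, 2 had such spots within 75 µm, up to 4, and within 300 µm the most was 7.

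The lowest ratios held likely artefacts of the control array, judged by the placement of their spots. Of the 15 lowest, 6 had their spot in a patch of adjacent bright spots on that array. These were C14orf180 (log2 ratio −12.82), LOXHD1 (−12.60), GK3 (−9.88), CKLF (−8.87), PLPBP (−5.65) and KU-MEL-3 (−5.61), and the other probes of CKLF reached −0.45. SGPP1, a phosphatase of sphingosine-1-phosphate, had a log2 ratio of −5.73 and is doubtful too, as its only spot had 2 spots at least 16-fold brighter on the control array within 75 µm and 7 within 300 µm. Of the 8 others, MINDY4 had 1 such spot within 300 µm and the rest 0, as counted after the data were seen. BEND5 was 40.1-fold lower on the adriamycin array, the ephrin gene EFNB3 24.8-fold, the linker histone gene H1-1 22.9-fold, ANGPTL7 21.7-fold and DOCK1, an activator of RAC, 18.5-fold. NREP was 14.7-fold lower over probes from −4.13 to −3.88, COL1A1, the main chain of type I collagen, 14.4-fold, and MINDY4 14.2-fold. Apart from NREP, the processed signals of these genes on the adriamycin array ran only from 28.0 (BEND5) to 59.9 (DOCK1). They lay below the highest negative control spot there, 828, so the size of those ratios is uncertain. When spots in patches were left out, a choice made after the data were seen, all 15 of the highest and 9 of the 15 lowest genes remained. Of genes well above background on the control array only, ADAM29, CNGA2 and EMX2 had their spots in patches. LRMDA was at least 14.9-fold lower and FGFBP1, a binding protein of fibroblast growth factors, at least 14.02-fold lower on the adriamycin array. Both bounds follow the rule above and are no strict limits either. The lowest spot called well above background on the adriamycin array had a signal of 19.9, and the highest negative control spot there 828.

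Spots that differed strongly were unevenly placed on the arrays. Of 145 spots at least 16-fold brighter on the control array, 48 had 3 or more such neighbours within 75 µm, and they formed the patches that hold LOXHD1, C14orf180 and the other genes named above. Of 923 spots at least 16-fold brighter on the adriamycin array, 659 lay in rows up to the middle of the array and 264 past it. Of the 2560 genes at least 2-fold higher, 108 had a spot in a patch, as had 55 of the 1940 at least 2-fold lower.

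**Figure D2:**
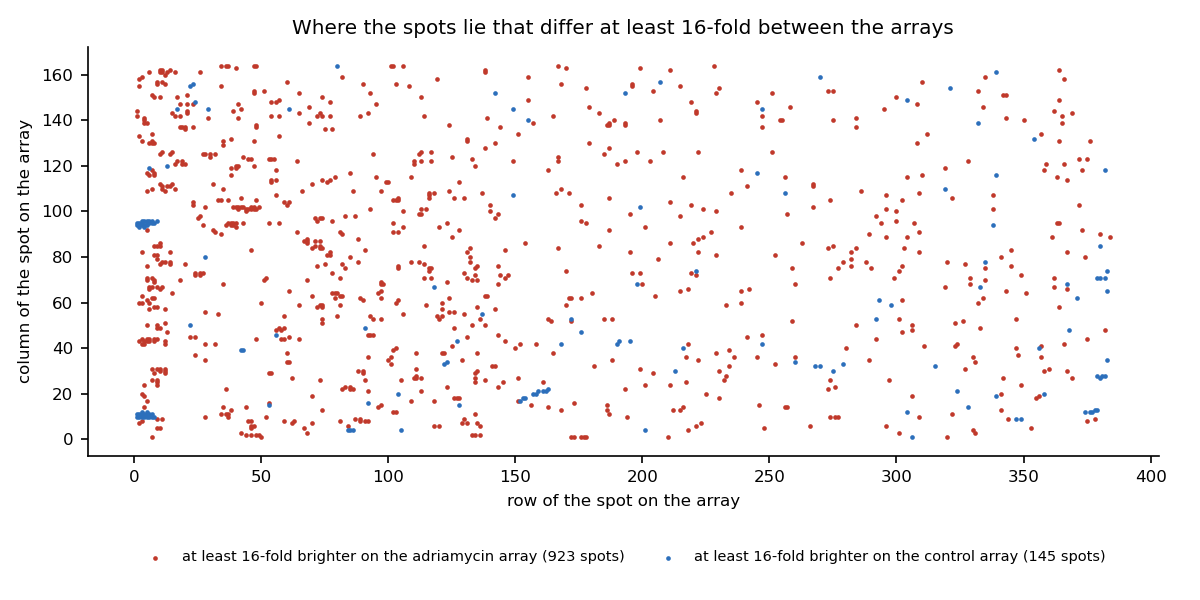
Position of the spots whose signals differed at least 16-fold between the arrays, with the row of the spot on the x axis and its column on the y axis. Red points are the 923 spots brighter on the adriamycin array, 659 of them in rows up to the middle, and blue points are the 145 spots brighter on the control array, of which 48 lie in patches.

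Targets of the transcription factor p53 stood highest of the gene lists. Of 37 measured members, 27 were at least 2-fold higher and 0 at least 2-fold lower, and the median log2 ratio of 1.36 lay above those of all 10000 random lists matched on level. Besides GDF15, the largest were TP53I3, a quinone oxidoreductase gene (log2 ratio 5.18), PLK3, a polo-like kinase gene (3.99), and TIGAR, a regulator of glycolysis (3.05). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was 2.25-fold higher (1.17). MDM2, the ubiquitin ligase of p53, had a log2 ratio of 0.44 with its 4 probes from 0.19 to 0.61. The BCL2 family and death receptor list had 10 of 29 members at least 2-fold higher and 1 lower (median 0.40, 99.45th percentile). Its largest were the BH3-only genes PMAIP1 (3.45), BIK (2.56) and BBC3 (2.17) and the death receptor gene TNFRSF10A (2.41). The list is not separate from the p53 list, as BBC3, BAX, FAS, TNFRSF10B and TNFRSF10C belong to both. Of the drug's own targets, TOP2B was 2.90-fold lower (log2 ratio −1.53) and TOP2A had a log2 ratio of −0.54, each over 10 spots.

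The G2/M and G1/S lists of cell cycle genes had medians below the random range. In the G2/M and mitosis list, 24 of 40 genes were at least 2-fold lower and 0 higher, and the median of −1.17 lay below all 10000 random lists. PLK1 (−2.46), ASPM (−2.29), CCNA2 (−2.17, 10 spots) and CCNB1 (−2.03, 10 spots) had the largest ratios. PTTG1, at 0.71, was the 1 member above 0 and was picked out after its value was seen. The G1/S and DNA replication list had 7 of 42 genes at least 2-fold lower and 2 higher (median −0.43, 0.060th percentile). POLA1, a DNA polymerase subunit gene (−2.74), and the helicase subunit genes MCM6 (−2.18) and MCM3 (−2.01) were lower, while PCNA, the sliding clamp, was higher (1.91, with 3 probes from 1.90 to 2.03). Double-strand break and crosslink repair genes were lower as a list, with 13 of 38 at least 2-fold lower and 1 higher (median −0.73, 0.010th percentile). NBN (−1.76), BRIP1 (−1.48) and BARD1 (−1.44) were lower and RAD51C higher (1.78). Replication-dependent histone genes went both ways, 11 of 54 at least 2-fold higher and 11 lower, with a median of 0.15 at the 95.5th percentile. That median changed sign under median scaling, and the list lay above the random range under 6 of 13 alternatives. H2AC7 (2.73) and H1-2 (2.28) stood at one end and H1-1 (−4.52) and H2AC13 (−1.91) at the other. Probes of such near-identical genes are uncertain. Among replication-independent histones, H2AJ (2.21) was higher, H2AX was lower (−1.70) and H1-10 stood at −0.88, with a list median of 0.17 over 10 genes at the 80.2nd percentile.

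The lists of interferon-stimulated and NF-kB genes had medians above the random range. The list of interferon-stimulated genes had 11 of 27 measured members at least 2-fold higher and 2 lower, with a median of 0.91 above all 10000 random lists. ISG15, a ubiquitin-like modifier (4.20), IFIT3 (2.95) and HERC5 (2.57, 10 spots) were higher, and IFI44 was lower (−3.45). The NF-kB and inflammatory cytokine list had 12 of 26 members higher and 2 lower (median 0.66, 99.99th percentile), with IL1B (4.92, 10 spots), IL6 (2.44), CSF2 (2.23) and TNFAIP3, an inhibitor of NF-kB (2.01), at the top. Of immediate early and AP-1 genes, 11 of 28 were at least 2-fold higher and 2 lower (median 0.41, 99.4th percentile). EGR2 (5.52, with a control signal of only 15.9), the phosphatase genes DUSP5 (3.33) and DUSP6 (3.16) and ATF3 (3.08) led it, and the 4 probes of ATF3 ranged from 0.09 to 3.14. This list fell within the range of random lists with the stricter filter on dim probes, with the probe of smallest ratio, and in the rows past the middle of the array. Complement genes had 6 of 15 members higher and 2 lower, with a median of 0.34 inside the range of random lists (94.9th percentile). CLU (3.49), C3 (2.12) and CD46 (1.70) were higher and CFD lower (−2.92). Immune cell markers, kept as a list of another cell type, had 4 of 7 measured members higher and 1 lower (median 1.23, 99.3rd percentile). CD14 (2.36), ITGAM (2.15), CD3D (1.89) and CD74 (1.23) led it at control levels of −2.77 or lower. With the stricter filter on dim probes 2 members were left, with a median of −0.48. The list also lay within the random range with normexp and with no filter on dim probes.

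Of the stress lists, that of NRF2 and antioxidant genes had 5 of 26 members at least 2-fold higher and 0 lower (median 0.50, 99.96th percentile). After AKR1B10, its largest were GPX3, an extracellular glutathione peroxidase gene (2.23), OSGIN1 (1.78) and HMOX1, heme oxygenase (1.41). Heat shock protein genes had 6 of 21 members higher and 1 lower (median 0.35, 98.6th percentile). HSPB8 (2.79), HSPA6 (1.77, other probe 0.33), HSPA1B (1.77) and HSPA1A (1.16) led them. That list was within the random range under 5 of 13 alternatives. Autophagy and lysosome genes had 8 of 30 members higher and 2 lower, with a median of 0.60 above all 10000 random lists. NEU1, a lysosomal sialidase gene (1.66), GABARAPL2 (1.56), MCOLN1 (1.499) and MAP1LC3A (1.31) were its largest. In the rows past the middle of the array, this list had a median of 0.036, within the random range. Metallothioneins, small metal-binding proteins, were the lowest list. Of 10 measured genes, 8 were at least 2-fold lower and 1 higher, and the median of −1.52 lay below all 10000 random lists. MT1X (−2.20), MT1H (−1.99), MT1L (−1.98) and MT1B (−1.97) were among the brightest genes of the control array, with levels from 7.54 to 8.14. These genes are near-identical in sequence, and the other probe of MT1X gave 0.28. Cholesterol synthesis and uptake genes had 6 of 26 members lower and 4 higher (median −0.55, 0.150th percentile). SQLE (−1.60) and LSS (−1.495, other probe −0.0010) were lower and TM7SF2 higher (2.34, 10 spots). In the rows past the middle of the array, its median was −0.085, within the random range. The integrated stress and unfolded protein response list showed no shift as a whole (6 of 26 higher, 2 lower, median −0.052, 44.0th percentile), although CHAC1 (2.43), ATF5 (1.37), DDIT3 (1.33) and DNAJB9 (1.22) were higher.

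Genes of the pigment epithelium itself were mostly within 2-fold where measured on both arrays. Of 32 members, 22 were so measured, of which 4 were higher and 1 lower (median 0.025, 62.2nd percentile). Another 4 were well above background on the adriamycin array only and 1 on the control array only. The median ranged from −0.279 to 0.377 over 13 alternatives, within the random range under each. STRA6, the receptor for retinol-binding protein (3.69, other probe 1.69), PMEL, a melanosome matrix protein (1.27), and the retinol dehydrogenase gene RDH5 (1.25) were higher, and EZR, which encodes ezrin, was lower (−1.07). The list of epithelial to mesenchymal transition and fibrosis had 7 of 28 members lower and 3 higher (median −0.37, 1.29th percentile), and lay within the random range without a filter on dim probes. Besides COL1A1 (−3.84), THBS1 (−1.998) and COL5A2 (−1.81) were lower, and COL6A1 was higher (2.62). The list of YAP and TEAD targets, which also holds YAP1, WWTR1, TEAD1 and TEAD4 themselves, had a median of −0.53 at the 0.240th percentile. Of its 20 members, 3 were higher and 3 lower. CRIM1 (−1.22) and CCN2 (−1.04) were lower, and ANKRD1 (2.24) and AJUBA (1.06) higher. Matrix proteases and their inhibitors, a list that also holds IGFBP genes, had 5 of 21 members higher and 2 lower (median 0.59, 99.95th percentile). PLAT, tissue plasminogen activator (3.46, 10 spots), SERPINE2 (2.21), CTSL (1.83, other probe 0.26) and TIMP4 (1.79) led it. Feedback genes of TGF-beta, WNT and NOTCH signalling had 7 of 24 members higher and 1 lower, with a median of 0.28 at the 96.2nd percentile. JAG1, a NOTCH ligand (3.02), ID2 (2.86), NOTCH3 (2.67) and SP5 (2.52) were its largest. Among angiogenic and epidermal growth factors, 5 of 21 were higher and 4 lower (median 0.10, 71.9th percentile). That median was 0.520 and above the random range with no filter on dim probes, but −0.523 and below it with the stricter filter. PGF and AREG stood far above the rest, while FGF5 (−2.25) and PDGFC (−1.96) were lower.

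**Figure D3:**
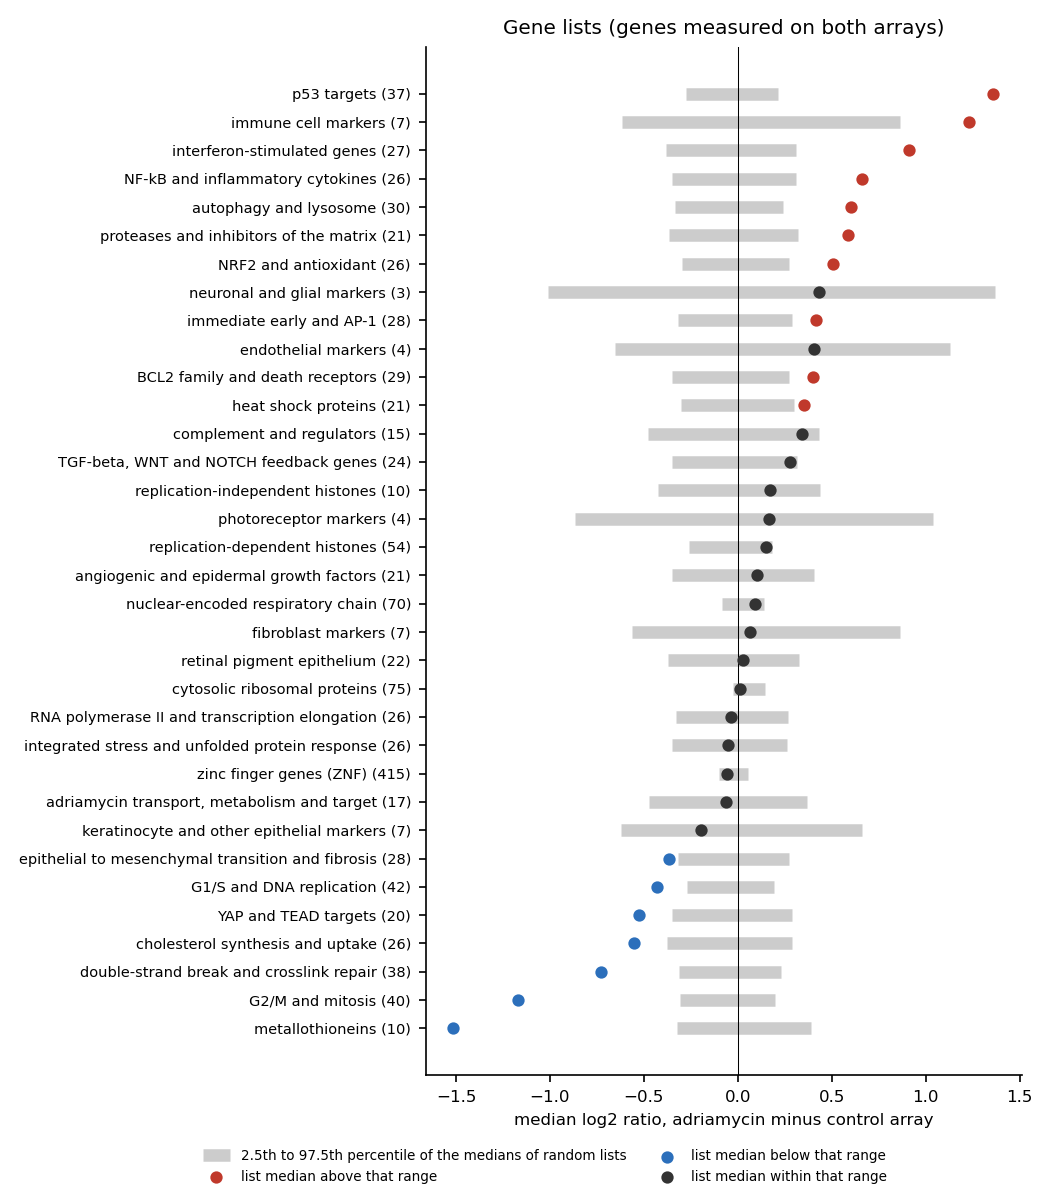
Median log2 ratio, adriamycin minus control array, of each of the 34 gene lists (points), with the number of genes measured on both arrays in brackets; grey bars span the 2.5th to the 97.5th percentile of the medians of 10000 random lists of the same size and level. The medians of 10 lists lie above their bar, led by p53 targets at 1.36, and those of 7 lie below it, with metallothioneins lowest at −1.52.

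All 75 measured cytosolic ribosomal protein genes lay within 2-fold, from RPL5 (−0.58) and RPS27A (−0.35) to RPS27 (0.36) and RPS15 (0.45), with a median of 0.0090 that changed sign under median scaling, cyclic loess, spike-in scaling and normexp. Of 70 nuclear genes of the respiratory chain, 67 lay within 2-fold (median 0.089, negative under median scaling); the exceptions included SDHA (1.03) and ATP5MC2 (−1.07), and NDUFA9 stood at −0.91. RNA polymerase II and elongation genes had a median of −0.036, with 3 of 26 higher and 1 lower. POLR2A, the largest subunit (1.86), POLR2H (1.62, other probe 0.080) and POLR2L (1.09) were higher. Genes of adriamycin transport, metabolism and target had 2 of 17 members higher and 2 lower (median −0.064). The transporter genes ABCC3 (2.001) and ABCC4 (−1.17) differed in direction, XDH was higher (1.95), and TOP2B was the other lower member. Zinc finger genes named ZNF, 415 in number, had a median of −0.058 at the 18.7th percentile, with 39 higher and 29 lower. ZNF296 (3.09), ZNF324 (2.86), ZNF561 (2.61) and ZNF699 (2.33) had their largest ratios.

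Of fibroblast markers, 7 of 9 were measured, all within 2-fold (median 0.063), with DCN at 0.76, PI16 at 0.58, COL14A1 at −0.55 and MFAP5 at −0.59. Endothelial markers had 4 of 9 measured (median 0.40), with VWF at 1.01 (other probe 2.63), ROBO4 at 0.66, CDH5 at 0.15 and ESAM at −0.20. Photoreceptor markers had 4 of 14 measured (median 0.16). ROM1 was 15.6-fold higher over 10 spots (3.96), while PDE6G (0.72), NRL (−0.39, other probe −1.05) and PDE6B (−0.68) lay within 2-fold. Neuronal and glial markers had 3 of 12 measured, TUBB3 (0.99), SNAP25 (0.43) and RBFOX3 (−0.068), with a median of 0.43. Keratinocyte and other epithelial markers had 7 of 11 measured (median −0.20), with SFN, a 14-3-3 protein (4.46), and CLDN1 (1.77) higher and KRT15 (−0.95) and KRT10 (−0.68) within 2-fold. These 5 lists lay within the range of random lists, at percentiles of 51.9, 75.8, 68.3, 81.3 and 25.9 in that order. Such short lists had wide random ranges, for neuronal and glial markers from −1.01 to 1.37. Several of the named markers were dim on both arrays. Processed signals on the control and adriamycin arrays were 24.4 and 39.5 for DCN, 42.0 and 27.5 for COL14A1, and 29.8 and 25.0 for ESAM. Ratios of such dim genes are uncertain.

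Across the 34 lists, 10 lay above the 97.5th and 7 below the 2.5th percentile of random lists, where 1.70 lists outside that range come by chance if genes were independent. Genes of a list are often regulated together, so these percentiles describe the lists on these 2 arrays and carry no p-value. These sign changes were counted over 13 alternatives, without the value table as headed. The median changed sign under at least 1 of them for 14 of the 17 lists within the random range. Of the 17 lists outside it, 1 did so, the immune cell markers.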

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

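The tests in this part were chosen after the results they bear on were seen. The first concerns the deposited value table, which the comparison did not use for its main values. Its log2 ratios, with the columns as headed, correlated with those of the scanner files at −0.9934 across the 25639 probes well above background on both arrays, and at −0.981 across all 50739 matched probes. The headings of the table may be swapped: the column headed control matched the adriamycin array with a correlation of 0.9999, and with the scanner files as labelled the p53 targets, a list fixed before the data were examined, lay above all 10000 random lists. A swap of the scanner files would put these targets lower on the array labelled adriamycin, and their median log2 ratio there was 1.361. This argument takes it as given that adriamycin raises p53 targets, and no biological explanation of opposite tables was tested.

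A second pattern was the set of very bright spots on the control array alone, which included 6 of the 15 lowest named genes. Their placement is consistent with a local artefact, since 48 of the 145 spots at least 16-fold brighter on that array had 3 or more such neighbours, against at most 2 in 1000 shuffles of the positions. More transcript in the control cells would raise other probes of the same genes too. Of 37 genes with a probe in such a patch, 9 had other probes well above background on both arrays. Those 21 probes had a median log2 ratio of −0.160. Probes dim on either array were left out, which can draw that median towards 0. For the patch genes without such other probes, only the placement bears on the question. For the other 97 spots and for the genes outside patches, both explanations stay open.

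The last pattern was the uneven placement of spots far brighter on the adriamycin array. Of 308 negative control spots, which carry no human sequence, 8 were well above background on the adriamycin array and 2 on the control array, with highest signals of 828 and 23.9. A local artefact of the adriamycin array is a likely contributor: of spots of probes present 10 times, 3.34% in the rows up to the middle lay at least 1 above their probe's median on the log2 scale, against 0.46% in the rows past it. On the control array these shares were 1.35% and 1.96%. Whether that artefact makes the excess of higher over lower genes cannot be told apart from a difference between the cells. In rows past the middle 53.2% of the genes past 2-fold were higher, between an even split and the 56.9% of the main setting. The split also turned on the processing, so an even split is no fixed reference. Higher were 34.4% with median scaling, 51.3% with spike-in scaling and 63.5% with cyclic loess. The stricter filter on dim probes gave 50.7% and no filter 65.2%.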

How the results depend on the processing

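The alternatives on patches, on rows past the middle of the array and on the value table as headed were chosen after the data were seen. List medians and genes counted as moved where they shifted by more than 0.069, the spread of single spots, and counts where they differed by over 1.5 times. No paired analysis was possible because each group has 1 array. The alternative without saturated spots was not run, as no spot was saturated.

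Against 2560 genes higher and 1940 lower, the counts were 6455 and 3438 with no filter on dim probes, 1155 and 1125 with the stricter filter, 4377 and 4063 at 1.5-fold, 819 and 302 at 4-fold, and 1316 and 1156 in rows past the middle, as these settings count more or fewer genes by construction. The split of calls differed too, with 65.2% higher with no filter and 50.7% with the stricter filter. Median scaling gave 3328 lower genes and 34.4% of calls higher. Normexp gave 1783 higher and 1382 lower genes. Of the 4494 main calls measured under it, 3130 stayed past 2-fold on the same side. Spike-in scaling gave 2343 higher and 2220 lower genes, or 51.3% of calls higher, and cyclic loess 63.5%. The p53 target median of 1.361 became 1.290 with normexp, 1.058 with median scaling, 1.463 with cyclic loess, 1.286 with spike-in scaling, 1.262 with the probe of smallest ratio and 1.195 past the middle. The G1/S median of −0.432 became −0.736 with median scaling, −0.347 with cyclic loess, −0.507 with spike-in scaling and −0.587 past the middle. The G2/M median of −1.172 became −1.476 with median scaling, −1.247 with spike-in scaling, −1.254 with the mean over probes and −1.340 past the middle. The median of replication-dependent histones, 0.150, became 0.307 with normexp, −0.154 with median scaling, 0.075 with spike-in scaling, 0.261 with no filter, 0.360 with the stricter filter, 0.223 without patches, 0.389 past the middle and −0.147 with the value table as headed. Apart from median and spike-in scaling, which move every gene alike, the cause was not tested.

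With the value table's columns as headed, each list outside the random range changed sign, by construction. The medians were −1.407 for p53 targets, 0.403 for G1/S, 1.187 for G2/M, 0.708 for break repair, −0.410 for the BCL2 family, −0.426 for immediate early genes, −0.594 for NF-kB, −0.901 for interferon-stimulated genes, −0.604 for matrix proteases, −0.530 for NRF2, −0.318 for heat shock, 1.505 for metallothioneins, 0.524 for cholesterol, 0.369 for the mesenchymal list, 0.50 for YAP, −0.616 for autophagy and −0.941 for immune markers. Under the 13 other alternatives, 11 of the 17 lists outside the range kept their side under each. The exceptions were immediate early genes, heat shock, cholesterol, the mesenchymal list, autophagy and immune markers, the last at −0.479 with the stricter filter. Of the 17 lists within the range, 11 stayed there under each alternative. Replication-dependent histones left it under 6, growth factors under 2 on opposite sides (0.520 with no filter and −0.523 with the stricter one), photoreceptor markers and TGF-beta, WNT and NOTCH genes under 2 each, and complement and zinc finger genes under 1 each. Of 139 named genes past 2-fold, 128 stayed past it on the same side with median scaling, 130 with normexp and 136 with the value table matched to the arrays. Most of these genes were named for the size of their ratios, so they do not stand for all calls. MT1X changed sign, to 0.277, with the probe of smallest ratio and past the middle, where its other probe lies.

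Signal over background limits the dim genes: 1955 genes were well above background on the control array only and 1695 on the adriamycin array only, so they have bounds at most.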

Other observations

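A scan of gene families by the stem of their symbols, made after the data were seen, found groups that stood apart, some of which share members with the lists fixed before the data were examined. Of 187 stems with at least 10 measured genes, noncoding ones included, 22 had medians above the 97.5th and 21 below the 2.5th percentile of matched random lists, where 4.67 on each side come by chance if genes were independent. Apart from SNORD, the families described here are a selection of those 43. Values are for their protein-coding members unless they are families of noncoding RNAs. Among those with medians below the random lists, the SRSF genes, splicing factors of the serine and arginine rich class, had a median log2 ratio of −0.97, with 4 of 11 at least 2-fold lower and 0 higher. SRSF2 (−2.46), SRSF3 (−2.13), SRSF7 (−1.98) and SRSF1 (−1.91) were the lowest. Kinesin genes (KIF) had a median of −0.84 with 8 of 29 lower and 1 higher, from KIF14 (−2.56) to KIF17 (1.60), and 4 of them belong to those lists. The medians were −0.61 for CEP genes of the centrosome (10 of 37 lower and 4 higher) and −0.61 for EXOSC genes of the RNA exosome (4 of 10 lower and 0 higher). LSM genes of RNA processing had a median of −0.53 with 0 of 12 past 2-fold and 2 above 0, and TIMM genes of mitochondrial import a median of −0.62 with 1 of 14 at least 2-fold lower and 5 above 0. Each of these medians stayed negative in all settings with the arrays as labelled.

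Among the families with higher medians, the dehydrogenases named DHRS had a median of 0.93 with 5 of 10 at least 2-fold higher, and besides DHRS2, DHRS13 (2.39) and DHRS7 (1.91) stood out. Genes named IL, mostly interleukins and their receptors, had 17 of 44 higher and 5 lower (median 0.67), 4 of the 44 belonging to the fixed lists, with IL17RB (4.05) and IL11RA (2.78) higher and IL1R1 lower (−2.04). The WNT receptors named FZD had a median of 1.09 with 5 of 8 higher, and of 0.477 in the rows past the middle of the array. Over all 10 genes of that stem, noncoding ones included, the median of 0.84 changed sign to −0.14 in those rows. TNF receptors (TNFRSF) and DUSP phosphatases stood apart in the scan, but their protein-coding members lay within the range of random lists. Of the former, 6 of 15 were higher and 0 lower (median 0.39, 94.1st percentile), among them TNFRSF8 (1.93) and TNFRSF14 (1.62), and 3 of the 15 belong to the fixed lists. Of the latter, 6 of 21 were higher and 0 lower (median 0.26, 92.3rd percentile, and −0.042 with median scaling), with DUSP26 at 4.57, and 5 of the 21 belong to the fixed lists. Small Cajal body RNAs (SCARNA) had 6 of 17 higher and 0 lower (median 0.68). The small nucleolar RNAs named SNORA had 22 of 82 higher and 4 lower (median 0.32, and 0.012 with median scaling). Those named SNORD did not share this, with 4 of 105 higher and 17 lower. Their median of −0.018 lay within the range of random lists (28.3rd percentile). The genes of this paragraph and the last were picked out after their values were seen.

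The replication-dependent histone genes differed by class. The 30 genes for H1, H2A and H2B had a median log2 ratio of 0.86 and the 24 for H3 and H4 of −0.34. Their difference of 1.197 ranged from 0.883 to 1.505 over the settings. The classes were pooled in this way after the members' values were seen, so a shuffle of the class names cannot test the difference, and near-identical probes of a class are not independent. Of the 12 H2B genes, 4 were at least 2-fold higher and 0 lower, while of the 12 H4 genes 0 were higher and 3 lower. The H2A genes went both ways, with 6 of 14 higher and 3 lower. Whether the transcripts of these classes differed or shared sequence among probes gives the same picture stays open.

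Neighbouring genes were examined with a test fixed before its result was seen. Among 12163 adjacent, non-overlapping pairs of measured genes without a shared symbol stem, 278 had both genes at least 2-fold higher, against a median of 221 and at most 255 in 1000 shuffles of the ratios over genes. Both genes were at least 2-fold lower in 205 pairs, against a median of 158 and at most 191. Examples, picked out after their values were seen, are ISG20 and HAPLN3 (3.60 and 5.27), OXER1 and HAAO (3.79 and 4.24), HES6 and PER2 (4.37 and 2.30) and CD82 and TP53I11 (2.53 and 3.61). The excess is consistent with a weak sharing of direction by position on the chromosome, with 278 pairs as the value that bears on it. Whether shared regulation, read-through transcription or gene density lies behind it was not tested.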
